A study of Mus musculus with 4 samples.

How the data were processed

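Joint tissue of DBA1 mice was profiled with TaqMan low density microRNA assays. Per the labels, the samples are 2 pools of joints from naïve mice and 2 pools from CIA mice, each of 6 mice. The labels number the pools of a group 1 and 2 and do not say that the pools came from separate mice, so p-values measure only the spread between these samples, which may be technical. Per the labels' protocols, total RNA was extracted with Trizol, 50 ng was reverse transcribed with Megaplex primer pools and preamplified, and PCR ran for 40 cycles on an AbiPrism real-time cycler. Settings for threshold and baseline were not given in the sources used here.

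The deposited table of raw values holds 768 numbered rows per sample, each with a raw Ct, per the file headers, or the word Undetermined. It also repeats 1 mean U6 Ct per sample. The U6 wells are not named there and were inferred by a search of all sets of 4 rows within 1 cycle of that value. Only 1 set of 4 wells had a mean equal to it within 1e-05 cycles in every sample. The SD of those wells was 0.098, 0.060, 0.079 and 0.069 cycles in control 1, control 2, CIA 1 and CIA 2. Undetermined cells numbered 278, 203, 273 and 213 in the same order, and 1 further row held a stray word in control 1 and an empty cell in CIA 1. The authors' second table gives a fold per row, the ratio of CIA to control after 2 to the power of minus the Ct relative to a housekeeping gene, averaged over the 2 samples of a group, per the file headers. The ratio of arithmetic means of that quantity relative to U6 matched all 441 deposited folds within 0.1%, and a ratio of geometric means matched 16. An arithmetic mean gives more weight to the sample in which an assay is higher relative to U6. The deposited fold and the geometric one lay on opposite sides of 1 in 22 assays and differed by over 1.5 times in 54.

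The rows were taken as 2 card blocks of 384. The files do not state this. It was inferred because all 1148 numeric cells of the first block and 0 of the 955 of the second are followed by a blank, and because wells at the places of the U6 wells in the second block have Ct values from 14.1 to 16.6. Assays with a Ct under 35 in all 4 samples, without the 4 wells that make up the deposited U6 value, were tested, 241 in the first block and 178 in the second. The 4 wells at the same places of the second block stayed among the tested assays, since the files do not name them. Each sample was centred on the mean Ct of these assays in each block, and the sign was turned, so that values are on a log2 scale with an assumed doubling per cycle. The groups were compared with limma 3.58.1 (lmFit and eBayes, group as the only term) in R 4.3.3, with Benjamini-Hochberg adjustment. The prior degrees of freedom were 2.80, and the median standard error of a difference was 0.67. A two-sided exact permutation test of 2 samples against 2 cannot give a p under 0.333 and was not used.

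The fit, the detection limit, most alternatives (exceptions are named with their results) and the rule for the assays described singly were fixed before the data were examined. The rule took the assays with the smallest p in each direction where none passed. Because numbers are not paired with names here, it was limited to 2 in each direction, and the parts of the rule that need names were not used. Lists of microRNAs by cell type and inflammation had also been fixed and were not tested for the same reason. The count of assays separated by at least 2-fold (the lowest sample of a group at least 1 log2 unit above the highest of the other), the ranges of mean Ct and the comparisons within sample numbers were chosen after the data had been examined.

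The procedure was tested on simulated data, with 100 of 419 assays changed and 20 simulations per size of change. The noise level was estimated from the data and its variation between assays was assumed, so the recoveries are a guide only. With the measured difference between samples 1 and 2 included, the procedure recovered 0% of 2-fold changes, 0% of 4-fold, 0.05% of 8-fold and 64.65% of 16-fold changes. Without a difference between the numbers it recovered 0.35%, 32.9%, 90.25% and 96.8%. With the measured difference between the numbers and the number added to the fit as a block, it recovered 0.8%, 32.4%, 88.9% and 96.6%, with a mean of 0.5, 4.5, 4.6 and 6.65 false calls per simulation. Without the block the mean was 0.05, 0, 0 and 0.55 false calls. In the measured data the fit with the block had prior degrees of freedom of 2.43, fewer than the simulation assumed. The recoveries with the block may therefore be too high. The alternatives were other references (U6, median, quantile normalization, none, both blocks together), other detection limits, other limma settings, the sample number as a block, and each sample left out in turn.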

Results

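MicroRNA levels were measured by reverse transcription and TaqMan real-time PCR in joint tissue of DBA1 mice. The 4 samples were 2 pools of joints from naïve control mice and 2 pools from mice with collagen-induced arthritis (CIA), a model of inflammatory joint disease in which animals are immunised with collagen. Each pool held tissue of 6 mice, and the pools of each group were numbered 1 and 2. The value of an assay was its threshold cycle (Ct), the PCR cycle at which its fluorescence crossed a threshold, so that a lower Ct stands for more template and a step of 1 cycle for about 2-fold. The comparison between the groups asks which small RNAs differ in level between arthritic and healthy joints. The files used here number the assays and do not pair the numbers with microRNA names, so assays are described in groups and 4 of them by number.

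A Ct was reached in 489 rows in control sample 1, 565 in control sample 2, 494 in CIA sample 1 and 555 in CIA sample 2. A Ct under 35 was taken as detected. By that limit 468 and 534 rows were detected in control samples 1 and 2, and 473 and 512 in CIA samples 1 and 2. The group means were 501 ± 46.7 rows in control and 492.5 ± 27.6 rows in CIA joints (SD, n = 2 each), a difference smaller than the spread within either group. In all 4 samples 423 rows were detected, and in no sample 192.

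Part of the assays stood several-fold apart between CIA and control joints, in both directions, while no single assay passed the test, which had low power. Of the 419 assays tested, 26 were higher in each CIA sample than in either control sample by at least 2-fold. Their median difference was 2.31 on the log2 scale, with a range of 1.39 to 5.71. Another 35 assays were lower in each CIA sample than in either control sample by at least 2-fold, with a median log2 difference of -1.98 and a range of -3.18 to -1.25. Together these 61 assays made up 14.6% of those tested. Splitting the 4 samples by number instead separated 54 assays by the same criterion, and the third possible split separated 0. Over all tested assays the median log2 difference between CIA and control joints was -0.05, and the quartiles were -0.81 and 0.81.

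The balance of higher and lower assays depended on the reference. Relative to U6, a small nuclear RNA commonly used as a reference in such assays, 33 assays were separated upward and 21 downward, and the median log2 difference was 0.24. With raw Ct the counts were 36 and 18, and with each sample centred on its median Ct they were 34 and 30. Another alternative, chosen after the data had been examined, took a reference for each block of rows. It was U6 in the first block and the unnamed wells at the same places in the second. The counts were then 29 and 30. In control sample 1 those unnamed wells ranged from Ct 15.3 to 16.6.

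In limma's moderated test, 0 of the 419 assays had an adjusted p under 0.05, and the smallest adjusted p was 0.192. Group was the only term of that fit, so the difference between samples 1 and 2 counted as noise. In simulations with that difference the fit recovered 0% of 4-fold and 0.05% of 8-fold changes. The 0 calls therefore do not show that changes are absent. At an unadjusted p under 0.05 there were 58 assays, 27 higher and 31 lower in CIA joints, where chance gives 20.95 if the 4 samples vary independently. An unmoderated linear model per assay gave 0 assays after adjustment and 54 before it. With the sample number added to limma as a block, 0 assays passed after adjustment and 109 had an unadjusted p under 0.05. Over 18 fits with the block, which differed in scaling and detection limit, 12 gave 0 calls and 6 gave 31 to 105. Without the block, the limma count at an unadjusted p under 0.05 fell whichever of the 4 samples was left out, which leaves 1 sample in a group. It fell least without CIA sample 1, and without control sample 1 it fell below the count given by chance. Without control sample 1, 5 assays passed at an adjusted p under 0.05, and without control sample 2, 1 assay passed, with the lone control sample assumed to vary like the CIA samples. The groups did not overlap in 192 assays, or 45.8%, where chance gives 33.3% for 2 samples against 2 if all 4 samples vary independently. Splitting the samples by number left 183 assays without overlap, and the third possible split left 44. Each assay lacks overlap in only 1 of these splits, so the counts are not separate observations.

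Among the assays with the smallest p, assay 334 was detected about 4 cycles earlier in CIA joints, at a Ct of 28.1 ± 0.16 against 32.4 ± 0.11 in control joints (SD, n = 2 each). After centring it was 14.7-fold higher in CIA joints, a log2 difference of 3.88 with a standard error of 0.57. Assay 133 was 14.5-fold higher (log2 difference 3.86, standard error 0.66), with a Ct of 28.7 ± 0.85 in CIA and 32.9 ± 1.09 in control joints. In the other direction, assay 364 was 7.74-fold lower in CIA joints, with a log2 difference of -2.95 and a standard error of 0.53. Its Ct was 29.2 ± 0.16 in CIA and 26.7 ± 0.35 in control joints. Assay 260 was 7.72-fold lower (log2 difference -2.95, standard error 0.57), with a Ct of 29.8 ± 0.50 against 27.2 ± 0.81. Each of the 4 assays differed in the same direction between every CIA and every control sample. They were picked by their small p in these samples, which favours such a separation and large folds. In limma with group as the only term each had an adjusted p of 0.192, so none passed. With the sample number added as a block each had an adjusted p of 0.0895 in limma. They passed, where tested, with the block and either both blocks of rows centred together, median centring or a limit of Ct 32. These fits were picked because they gave calls, and 12 of the 18 fits with the block gave 0.

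**Figure D1:**
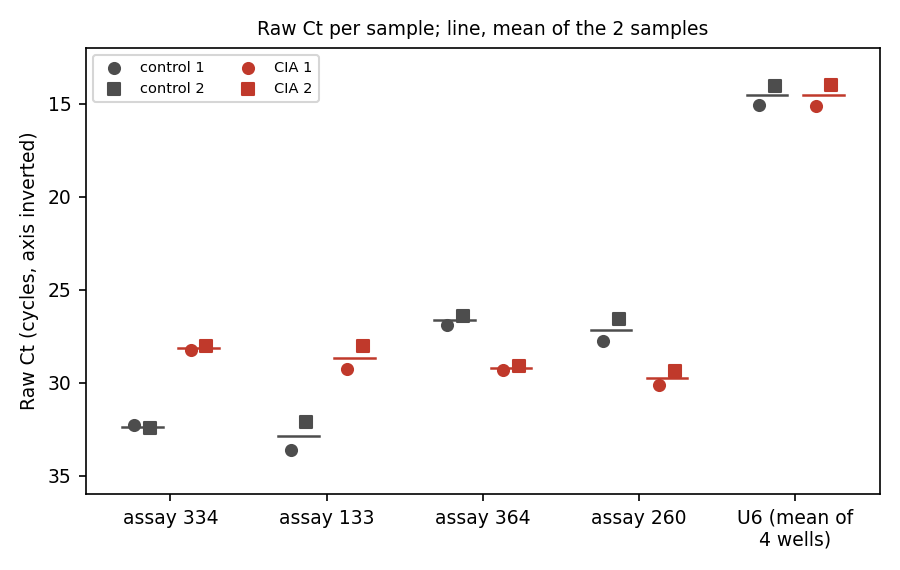
Raw Ct in cycles, on an inverted axis, of the 4 numbered assays and of U6 (mean of 4 wells) in each sample, with circles for samples numbered 1, squares for samples numbered 2, and a line at the mean of the 2 samples of a group. Assays 334 and 133 have a lower Ct in both CIA samples, assays 364 and 260 a higher Ct, and the U6 group means differ by 0.013 cycles.

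Separated assays were found from early to late Ct. Among the 54 assays with a mean Ct under 20 over the 4 samples, 4 were higher and 7 lower in CIA joints by the 2-fold criterion. The median log2 difference of these 54 was -0.25, with a range of -2.89 to 2.93. Among the 245 assays with a mean Ct from 20 to 28, 11 were higher and 21 lower. Among the 120 with a mean Ct of 28 or later, 11 were higher and 7 lower. The rows fall into 2 blocks of equal length, which were centred separately. The first block held 19 higher and 19 lower assays, or 15.8% of those tested in it, and the second 7 higher and 16 lower, or 12.9%.

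Samples of the same number were also compared with each other, because the samples numbered 1 and those numbered 2 differed in U6 level and in the number of detected rows. Between CIA sample 1 and control sample 1, 80 assays were higher and 83 lower by at least 2-fold. Between CIA sample 2 and control sample 2, 92 were higher and 98 lower. In both comparisons 42 assays were higher by at least 2-fold and 59 lower, while 4 assays differed by at least 2-fold in opposite directions. The sign was the same in 296 assays, or 70.6%. Across assays, which are not independent replicates, the log2 differences of the numbered pairs had a Pearson correlation of 0.63 and a Spearman correlation of 0.64. The Pearson correlation was 0.65 within the first block of rows and 0.61 within the second. Assay 334 was higher in CIA joints by 3.66 and 4.10 on the log2 scale in pairs 1 and 2, and assay 133 by 3.99 and 3.72. Assay 364 differed by -2.85 and -3.06, and assay 260 by -2.76 and -3.13. As these assays were picked from the same samples, the match of their pairs is no separate evidence.

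**Figure D2:**
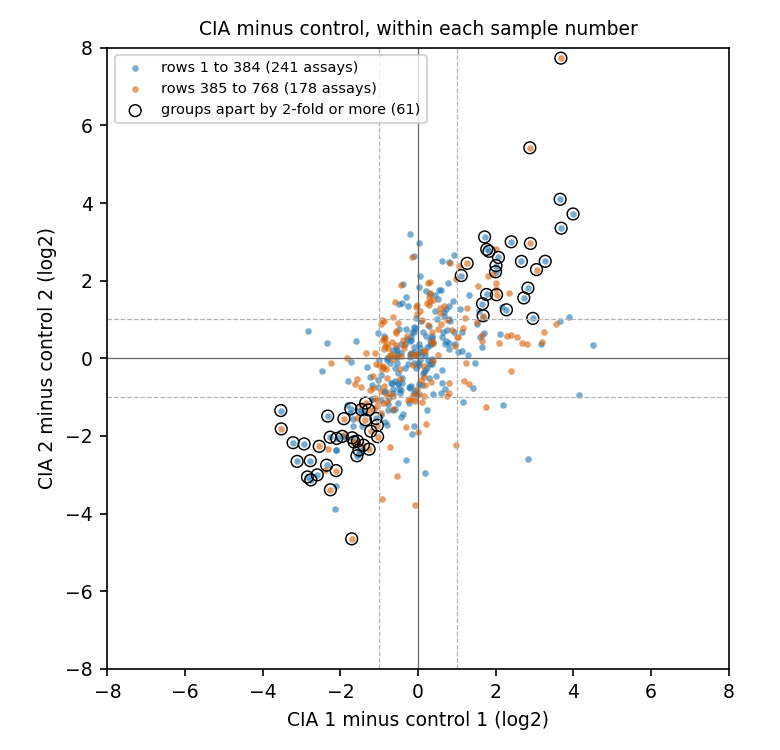
Log2 difference between CIA sample 2 and control sample 2 plotted against that between CIA sample 1 and control sample 1, 1 point per assay, blue for the first block of rows (241 assays) and orange for the second (178 assays). Dashed lines mark 2-fold, and open circles mark the 61 assays whose groups stand apart by 2-fold or more, 26 at the upper right and 35 at the lower left.

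The spread between samples of a group was wide. Between control samples 2 and 1 the log2 differences over the tested assays had an SD of 1.84, and between CIA samples 2 and 1 an SD of 1.81. The differences between CIA and control had an SD of 1.38 among samples numbered 1 and 1.48 among samples numbered 2. In the first block of rows these SDs were close to each other, at 1.40 and 1.35 between the samples of a group and 1.42 and 1.43 between CIA and control. In the second block they were 2.31 and 2.29 within a group and 1.33 and 1.55 between CIA and control. After centring, sample 2 was higher than sample 1 by at least 2-fold in both groups for 22 assays and lower for 61. In raw Ct the balance was the other way. By at least 1 cycle in both groups, 79 assays were earlier in sample 2 and 32 later. In 4 assays the centred value of sample 2 exceeded that of sample 1 by 8.22 to 12.44 on the log2 scale in both groups. Without these 4 the SDs within a group in the second block were 1.45 and 1.65.

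**Figure D3:**
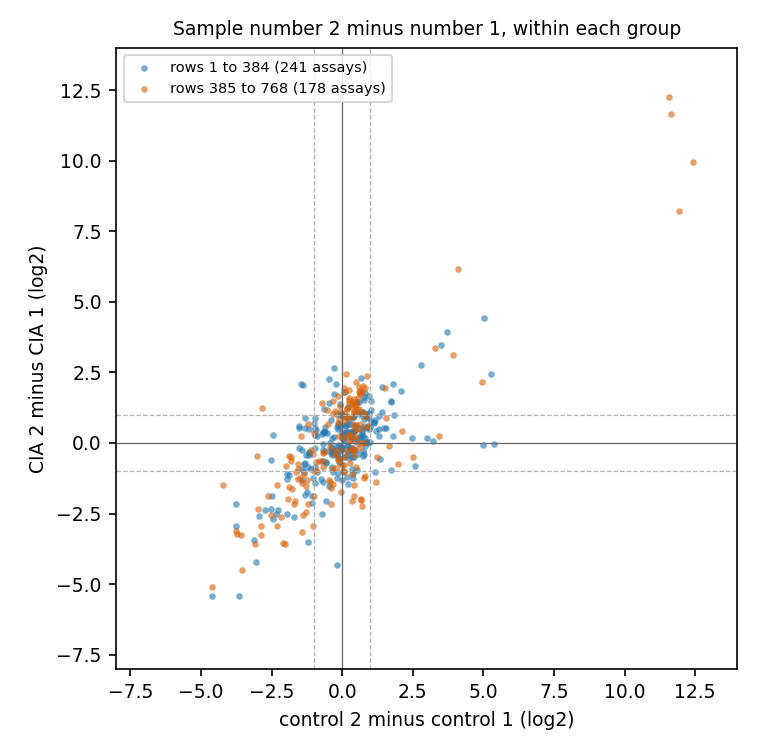
Log2 difference between CIA samples 2 and 1 plotted against that between control samples 2 and 1, 1 point per assay, blue for the first block of rows (241 assays) and orange for the second (178 assays), with dashed lines at 2-fold. The 4 points at the upper right, all from the second block, lie between 8.22 and 12.44 on both axes.

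Few rows were detected in only one of the groups. By the limit of Ct 35, 2 rows were detected in both CIA samples and in neither control sample, and 2 rows the other way round. With a limit of Ct 32 there were 12 such rows in all, and with Ct 38 there were 7. The rows detected only in CIA joints had a mean Ct of 33.4 ± 1.45 and 34.3 ± 0.38 (SD, n = 2 each). This makes them at least 2.27-fold and 1.28-fold higher there when the side past the limit is set to Ct 35. The rows detected only in control joints had a mean Ct of 33.1 ± 2.05 and 31.2 ± 2.05, at least 4.65-fold and 15.8-fold higher in control joints. Each of these rows still reached a Ct, from 35.5 to 38.9, in 1 sample of the other group, so it was not absent there. For comparison, 44 rows were detected in both samples numbered 2 and in neither sample numbered 1, and 8 rows the other way round.

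U6 gave a Ct of 14.5 ± 0.72 in control and 14.6 ± 0.79 in CIA joints (SD of the sample means, n = 2 each), a difference of 0.013 cycles. Within the numbered pairs U6 differed between CIA and control by 0.066 and -0.040 cycles. Between samples 2 and 1 it differed by -1.01 cycles in control and -1.12 cycles in CIA joints. Relative to the mean Ct of the assays detected in all samples in the first block, U6 was 10.16 ± 0.35 log2 units above the mean in control and 9.78 ± 0.47 in CIA joints, a difference of -0.38 that lay between the SDs of the groups in size. Within the numbered pairs this difference was -0.47 and -0.30. It was -0.65 without control sample 1, -0.13 without control sample 2, -0.05 without CIA sample 1 and -0.72 without CIA sample 2, and -0.16 with median centring.

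The authors' deposited table of fold changes gives 441 ratios of CIA to control, of which 269 are above 1 and 172 below, with a median of 1.24. At least 2-fold higher in the authors' deposited table are 121 assays, and 69 have a ratio of at most 0.5. The raw Ct relative to U6 put 111 of those 121 assays higher in CIA joints within both numbered pairs, and in 89 the groups did not overlap. Of the 69 assays, 63 were lower within both pairs and 44 had groups that did not overlap. The highest ratio in the authors' deposited table is 37.8 and the lowest 0.0503. Among its 5 highest ratios, 14.4 or more, the groups did not overlap in 4, and among its 5 lowest, 0.172 or less, in 3. The authors' deposited table gives 18.6 for assay 334, 18.5 for assay 133, 0.173 for assay 364 and 0.170 for assay 260. Over the 419 assays tested, the log2 ratios in the authors' deposited table and the differences computed here had a Pearson correlation of 0.967 and a Spearman correlation of 0.973 across assays. All 26 assays separated upward have a ratio of at least 2 in the authors' deposited table, and 33 of the 35 separated downward have one of at most 0.5. The deposited ratios and the differences computed here come from the same Ct values. These correlations and counts are therefore no independent evidence of a difference.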

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

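The 2-fold count was chosen after the data had been examined. So were, among the alternatives, the U6 of each block, the first block only and the combinations with a block. Leaving out the second-block wells at the U6 places or values written to over 6 decimals was also chosen then. In the second block, the U6 of each block stands for the unnamed wells at the U6 places. In 18 of the 20 alternatives without a block, limma gave 0 assays at an adjusted p under 0.05. Leaving out a sample gave 0 to 5, 5 without control 1 and 1 without control 2. It also gave 18 to 44 assays at an unadjusted p under 0.05, 52 to 66 separated upward and 53 to 69 downward, 21 to 29 rows detected in one group only, and correlations with the deposited folds of 0.707 to 0.876. Separation and detection counts rise by construction with fewer samples.

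The downward count was 21 relative to U6, 18 without normalization and 19 in the first block, where fewer assays were tested. The median log2 difference was 0.24, 0.22 and, for the U6 of each block, 0.11. The correlation with the deposited folds was 0.951 after quantile normalization, 0.957 at Ct 38, 0.941 with every reported Ct, 0.948 with the U6 of each block and 0.981 in the first block. Rows detected in one group only numbered 12 at Ct 32 and 7 at Ct 38. The correlation within sample numbers was 0.544 with every reported Ct. The cause was not tested. No alternative that tested them turned the sign of the 4 numbered assays (334 and 133 were not tested at Ct 32). Their choice by a small p in these samples makes a stable sign likely. Their adjusted p in limma without a block was 0.103 or more.

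The sample numbers give 2 pairs, and the labels do not say what a number marks. The differences between samples 2 and 1 in control and CIA joints had a Pearson correlation of 0.77 and a Spearman of 0.57 across assays, or 0.65 and 0.56 without 4 assays over 8 log2 apart. With the number as a block, limma gave 0 calls and 109 assays at an unadjusted p under 0.05. The block gave 72 and 132 with both card blocks centred together, 87 and 127 with median centring, and 39 and 118 at Ct 32. These 3 were picked because they gave calls, from 36 fits (6 scalings, 3 detection limits, with and without the block). All 18 without the block gave 0 calls, and of the 18 with it 12 gave 0 and 6 gave 31 to 105. The 4 numbered assays had an adjusted p of 0.0895 with the block alone and passed wherever tested in the 3 combinations, at 0.0451 with Ct 32, 0.000311 to 0.00407 with both card blocks together, and lower with median centring, whose prior degrees of freedom were infinite.

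Not run, for want of names or flags in the files used here: the mean of all small RNA controls, mouse-named assays only, flagged wells left out, estimated correlation for list tests, 1 arm per precursor.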

Other observations

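All tests of explanations below were chosen only after the results they bear on had been seen.

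Samples with the same number deviated together in both groups. The SD of the difference between samples 2 and 1 was 2.31 in control and 2.29 in CIA joints in the second block and 1.40 and 1.35 in the first, but without the 4 assays that differed by 8.22 to 12.44 the second block gave 1.45 and 1.65. More template in the samples numbered 2 goes with their earlier U6 (-1.01 and -1.12 cycles) and with 44 rows detected in number 2 only against 8 in number 1 only. It also goes with 79 assays whose raw Ct was earlier there by at least 1 cycle in both groups. As the whole cause, more template would leave few assays later there. Yet 32 had a raw Ct later by at least 1 cycle in both groups, where unshared noise gives 1.04. Noise of single wells would not recur in other samples, yet the differences in control and CIA joints had a correlation of 0.797 among the 186 assays with a mean Ct under 25. Differences of single pools of mice would likewise not recur, since naïve and CIA pools hold different mice. The same correlation argues against them as the whole cause. A preparation or card batch and mice that differ by number in both groups alike stay open. They cannot be told apart, since the 52 rows detected in one number only could come from either. Template amount stays open for part of the pattern.

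A hypothesis is that part of the difference between CIA and control joints is shared by both numbered pairs although single assays did not pass the test. Noise of single wells would not recur, yet the differences of the numbered pairs, which have no sample in common, had a correlation of 0.63 across assays. It was 0.633 without the rows that hold a value written to over 6 decimals. Splitting the 4 samples by group separated 61 assays by at least 2-fold and the highest of the other splits, by number, 54. The remaining split separated 0. Only 1 of the 3 splits, the real one, gave as many as 61, and 3 splits are too few for a share under 0.05. Whether the shared part may come from arthritis, from other differences between the mice of the groups or from handling was not tested. The labels give no handling batch and do not say that the pools of a group came from separate mice. If these pools shared mice, any difference between the mice of the groups would recur in both pairs.

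Of 2103 numeric Ct values, 35 are written to over 6 decimals, 34 of them in the samples numbered 1 and 0 in the first block. They fall in 31 rows, of which 26 were tested and 3 were separated by 2-fold or more. In the samples numbered 1, 1 pair of rows has identical Ct values in both samples, and in those numbered 2 there are 0 such pairs.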
